A study of Rattus norvegicus with 6 samples.

How the data were processed

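Liver RNA of 6 male rats was hybridised to 1-colour Affymetrix rat expression arrays, 1 array per animal, with 3 animals on a control diet and 3 on a diet that contained epsilon-momfluorothrin, a pyrethroid insecticide, for 2 weeks. The animals were bought at 4 weeks of age, quarantined for 1 week and were 7 weeks old at sampling, per the labels. The sample titles and the treatment protocol give the dietary dose as 3000 ppm, whereas the sample characteristics, source names and descriptions give 5000 ppm, so the dose is left open and the treated group is called momfluorothrin throughout. The labels number the animals of each group as biological replicates 1 to 3. No label states that equal numbers mark a shared litter, cage or day, and the model carried no block.

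The deposited values are linear probe set intensities (signals) made with MAS5, per the submitters' processing notes; its version and settings are not given in the sources used here. Every array had the same trimmed mean of about 100 with 2% of the probe sets left out at each end, so the arrays had already been scaled by 1 factor each, and no further normalization was applied. The table held no detection calls. In their place a probe set was called dim in a group where its signal did not exceed the array median on any of the 3 arrays. A fold against a dim group is given as a lower bound against the array medians, while the tests used the signals as measured. The number of arrays, and not a read depth, limits the precision of each value.

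Of 31099 probe sets, 57 Affymetrix control probe sets were left out of the gene tests and fitted on their own. The remainder were kept where the signal exceeded the array median on at least 3 of the 6 arrays. This left 15778 probe sets. Gene names came from the platform annotation held by GEO, in which 20826 probe sets had 1 gene symbol, 436 had several and 9780 had none. Of the probe sets with 1 symbol, 20766 were matched to a rat gene table of assembly GRCr8, which was used for names only and updated 1 symbol. No gene was named from a probe set with several symbols. A gene was represented by its kept probe set with the highest mean log2 signal, whatever its test gave, which left 9200 genes.

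Signals were converted to log2 with no pseudocount and compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided, with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05 on the adjusted p. Signals are given as mean ± SD over 3 arrays, log2 differences as treated minus control ± SE, and adjusted p-values are those of this limma fit unless another test is named. Gene lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation. The fry test, which asks whether the members of a list move on balance in 1 direction without comparing them with other genes, was run beside it. The lists covered xenobiotic metabolism and transport, nuclear receptor targets, lipid, bile acid, glucose and amino acid metabolism, hormone axes, stress and inflammation, the cell cycle, liver zonation and the cell types that a piece of liver holds.

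The samples, tests, gene lists, alternatives and rule for naming genes were fixed before the data were examined. The rule named the 10 genes with the largest rise and the 10 with the largest fall past the threshold, excluding predicted loci, where all 3 treated arrays lay on one side of all 3 control arrays. It added up to 4 members past the threshold per gene list, or the 2 with the smallest p where none was, and Cyp2b1, Cyp2b2 and Cyp3a23-3a1 whatever their values. Camera had been written down without a variance trend. It was first run with a trend, and the result of both forms had been seen when the form written down was restored; the form with the trend, which put 5 lists past the threshold where the form written down put 1, is kept as an added alternative.

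The alternatives changed the filter on low signals, the scaling (quantile normalization or median centring), the pseudocount (16), the variance model, array weights, the rule for several probe sets of a gene, a replicate block and the set test, and left out each array in turn. A second quantile normalization, within kept probe sets, was added after seeing the data.

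The fit was tested on simulated arrays built from the measured means and residual SDs of the 15778 kept probe sets, with 200 probe sets changed in each of 20 runs. For the comparison of momfluorothrin with control it recovered 12.7% of the changes of log2 0.5, 52.3% of those of log2 1 and 88.4% of those of log2 2, and 4.36% of its calls were false. The simulated probe sets varied independently, which real genes do not. The replicates are separate animals per the labels, and labels give no hybridisation batch or date.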

Results

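Gene expression was measured in the liver of 6 male rats, 3 fed a control diet and 3 fed a diet with epsilon-momfluorothrin for 2 weeks, with 1 array per animal. The deposited signals had a trimmed mean of about 100 on each array. Array medians were 28.3 ± 1.18 in the control group and 25.2 ± 1.83 in the treated group (SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 against 3 allows, 2-sided). The 3' to 5' signal ratio of the Gapdh control probe sets, a measure of RNA and labelling quality, was 1.25 ± 0.025 in control and 1.25 ± 0.0267 in treated livers (exact permutation p = 0.8), and that of beta-actin was 2.49 ± 0.235 and 2.71 ± 0.37 (exact permutation p = 0.5). Over kept probe sets, arrays correlated at r = 0.964 to 0.97 within the control group, 0.972 to 0.974 within the treated group and 0.958 to 0.971 between the groups. The first principal component held 31.4% of the variance and separated the groups, with treated replicate 3 the farthest out.

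The comparison asked which liver transcripts differed after 2 weeks on the treated diet. Genes of xenobiotic metabolism and export were among the largest rises. Abcc3, an efflux pump for conjugated drugs and bile acids, rose from a dim control signal of 2.97 ± 0.0874 to 112 ± 10.7, at least 3.94-fold (SD, n = 3). Its adjusted p of 0.000861 in limma is that of the measured log2 difference of 5.23 ± 0.34 (SE), and the lower bound was not tested. The carboxylesterase gene Ces2c rose 3.91-fold, from 263 ± 37.3 to 1022 ± 53.9 (adjusted p = 0.000591 in limma), and Akr7a3, an aldo-keto reductase that acts on aflatoxin dialdehyde, rose 3.84-fold, from 374 ± 64.9 to 1432 ± 204 (adjusted p = 0.00202 in limma). Apoa4, an apolipoprotein of triglyceride-rich particles, fell from 3499 ± 415 to 1578 ± 194, a log2 difference of -1.15 ± 0.12 (SE, adjusted p = 0.0109 in limma).

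In all, 18 genes rose and 2 fell among the 9200 genes tested, 12 of them by at least 2-fold, and 27 of 15778 probe sets passed the adjusted threshold. At an unadjusted p under 0.05, 557 genes were higher and 569 lower. That balance moved with the processing. It was 702 to 410 with median centring, 582 to 465 with quantile normalization over all probe sets, and 664 to 790 without a filter. All 3 treated arrays lay on one side of all 3 control arrays for 1681 genes (18.3%, where chance gives 10%). The counts rested on single arrays, on the variance model and on the model having no replicate block. Without treated replicate 2 the counts were 3 genes higher and 1 lower, and without treated replicate 3 they were 5 and 2. With limma's eBayes without an intensity trend only Abcc3 and Ces2c passed, with no gene lower. A replicate block gave 10 genes higher, 9 of them among the 18, and 3 lower, 1 of them among the 2.

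**Figure D1:**
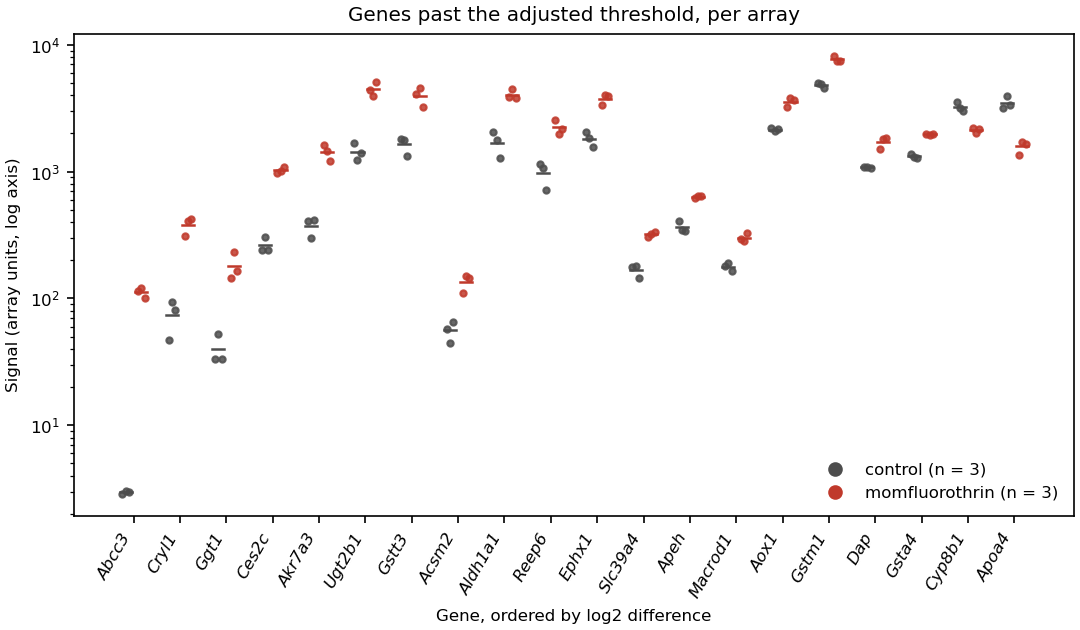
Signal of each gene past the adjusted threshold on each array (vertical log axis, array units), ordered by log2 difference; points are single arrays of the control (grey) and momfluorothrin (red) groups and horizontal bars are group means, n = 3 each. In all 20 genes the 3 treated arrays lie apart from the 3 control arrays; the control signal of Abcc3 is dim and is drawn as measured.

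Among phase I enzymes that are targets of the nuclear receptors CAR and PXR, 4 of 13 measured genes rose, also when adjusted over the list alone, and none fell. The other 9, among them every cytochrome P450 gene tested in this list, did not pass. Ces2c and Akr7a3 are given above. Aldh1a1, a retinaldehyde dehydrogenase, rose 2.41-fold, from 1694 ± 376 to 4029 ± 363 (adjusted p = 0.0186 in limma), and Ephx1, the microsomal epoxide hydrolase, rose 2.08-fold, from 1813 ± 240 to 3768 ± 343 (adjusted p = 0.0109 in limma). Of the 20 genes fixed for this list, 15 had a probe set of their own on the array and 13 were tested. Cyp2b1 and Cyp2b2 were not among those tested, so the set test does not cover them. The list had a median log2 difference of 0.07 and did not pass the set test (camera adjusted p = 0.071, and adjusted p = 0.975 with an estimated correlation). Under 7 of the other settings it did pass, with adjusted p as low as 0.00969 without a filter on low signals, and it also passed without control replicate 1 (adjusted p = 0.0289), control replicate 2 (0.0168) or treated replicate 3 (0.0174).

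Cyp3a23-3a1, a cytochrome P450 that is induced through PXR, was not among the genes that rose. Its signals were 7596, 8521 and 5835 in control replicates 1 to 3 and 6864, 6720 and 5718 in treated replicates 1 to 3, a log2 difference of -0.17 ± 0.14 (SE, n = 3, adjusted p = 0.657 in limma). No probe set measured Cyp2b1 or Cyp2b2 alone. A probe set annotated to both had signals of 3527, 2573 and 2177 in control and 5310, 4420 and 4964 in treated livers, a log2 difference of 0.85 ± 0.16 that did not pass the threshold (SE, n = 3, adjusted p = 0.107 in limma) although the groups did not overlap.

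Of 25 measured phase II genes, which encode enzymes that conjugate drugs and their metabolites, 4 rose and none fell. Adjusted over the list alone, 11 rose and 3 fell. Ugt2b1, a glucuronosyltransferase, rose 3.12-fold, from 1439 ± 223 to 4472 ± 561 (SD, n = 3, adjusted p = 0.00202 in limma). The glutathione transferases Gstt3, Gstm1 and Gsta4 rose 2.42-fold, 1.61-fold and 1.49-fold, with log2 differences of 1.28 ± 0.15, 0.69 ± 0.07 and 0.58 ± 0.07 (SE, adjusted p = 0.0185, 0.0109 and 0.0206 in limma). This was the only list of 34 past the set test (camera adjusted p = 0.000644, median log2 difference 0.21). The call was lost in the form of camera that estimates the correlation (adjusted p = 0.302). The estimate for this list was -0.01, below the preset 0.01, so a higher correlation among its members was not the reason for that loss. The reason was the smaller degrees of freedom of the estimated form, which the 6 arrays set. The unadjusted camera p was 1.9e-05 at the preset correlation and 0.00888 with the estimate. The number of lists past the test was 3 without control replicate 1 or without control replicate 2 and 5 without treated replicate 3. Other splits of the 6 arrays put up to 6 lists past the same threshold. In fry the adjusted p of phase II conjugation was 0.0139, and no other list was under 0.05. The CAR and PXR list and the transporters, both upward, had an adjusted p of 0.0737 there. In the mixed form of fry, which asks whether members change in either direction, 11 lists passed, among them phase I enzymes (adjusted p = 1.97e-05), transporters (6.45e-06) and bile acid synthesis (0.00491). Each of these lists holds a called gene.

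Among 15 measured drug and bile acid transporters, Abcc3 rose and the others did not pass the threshold. Adjusted over the list alone, 1 rose and 2 fell (median 0.02, camera adjusted p = 0.714). Among 14 measured genes of bile acid synthesis, Cyp8b1, the sterol 12-alpha-hydroxylase that directs synthesis towards cholic acid, fell from 3215 ± 266 to 2129 ± 90.9, a log2 difference of -0.59 ± 0.08 (SE, n = 3, adjusted p = 0.0443 in limma). That call was lost whichever of the 6 arrays was left out. No other member of the bile acid list passed over all probe sets; adjusted over the list alone, 2 rose and 1 fell (median -0.02, camera adjusted p = 0.95).

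The remaining large rises lay outside these lists. Cryl1, a crystallin-related dehydrogenase of the glucuronate pathway, rose 5.26-fold, from 74.5 ± 24.3 to 379 ± 59.5, and Ggt1, the gamma-glutamyltransferase that cleaves extracellular glutathione, rose 4.55-fold, from 39.7 ± 10.8 to 180 ± 46.4 (SD, n = 3, adjusted p = 0.0109 for both in limma). Acsm2, a medium-chain acyl-CoA synthetase, rose 2.42-fold from 56 ± 10.8 to 135 ± 20.8 (adjusted p = 0.0454 in limma), a call that was lost whichever array was left out. Reep6, a protein of the endoplasmic reticulum, rose 2.32-fold from 977 ± 225 to 2234 ± 299 (adjusted p = 0.0451 in limma), and its call was lost without control replicate 2 or any 1 of the treated replicates. It stayed past the threshold in 6 of the 12 alternatives that keep all arrays, the fewest of the called genes. A further probe set of Reep6 had a log2 difference of 1.08 ± 0.18. Without treated replicate 2, Abcc3, Cryl1, Ggt1, Gstt3, Aldh1a1, Ephx1, Gstm1 and Gsta4 no longer passed (adjusted p of up to 0.212 for these genes over all alternatives), whereas Ces2c, Akr7a3, Ugt2b1 and Apoa4 passed whichever array was left out. Without treated replicate 3, Cryl1, Ggt1, Aldh1a1, Ephx1, Gstm1 and Gsta4 were lost, without treated replicate 1 Gstt3, Aldh1a1 and Gsta4, and without control replicate 2 or 3 Gsta4.

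**Figure D2:**
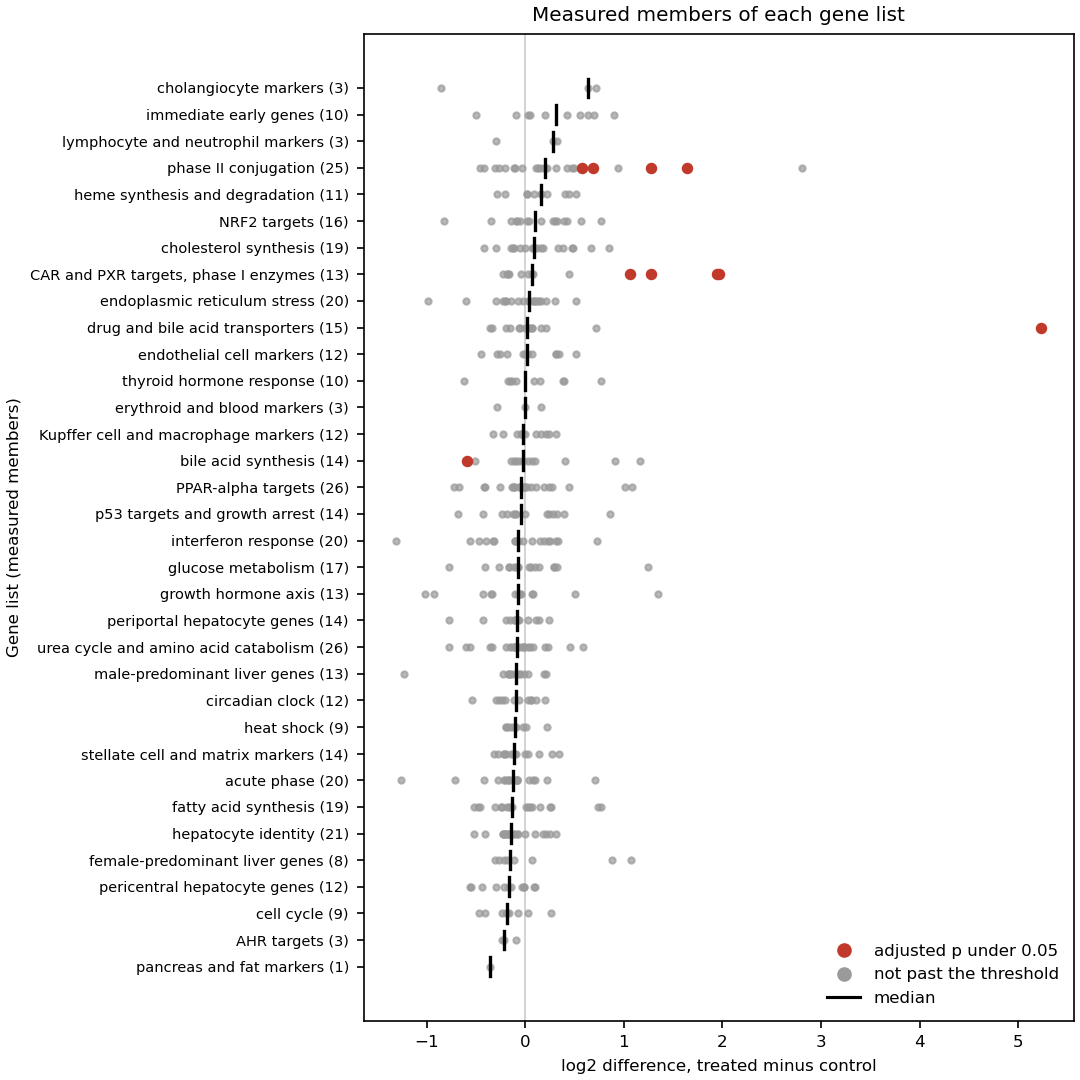
Log2 difference (treated minus control, horizontal axis) of each measured member of the 34 gene lists, with the number of measured members in parentheses; red points are genes with a limma adjusted p under 0.05, grey points the others, and black bars list medians. Red points lie to the right of 0 in the CAR and PXR, phase II and transporter lists, and Cyp8b1 in the bile acid list lies at -0.59.

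In the 30 other lists no member passed over all probe sets, and none of these lists passed the camera test in the main setting. Without control replicate 1 cholesterol synthesis passed upward (adjusted p = 0.0159), and without control replicate 2 pericentral genes passed downward (adjusted p = 0.00426). Without treated replicate 3 acute phase genes (adjusted p = 0.00193) and hepatocyte identity genes (0.0431) passed downward and immediate early genes upward (0.0431). Acute phase and pericentral genes also passed under the filter at the 70th percentile (adjusted p = 0.0162 and 0.0223). These 2 lists and hepatocyte identity genes passed downward in camera with an intensity trend, and immediate early genes passed upward with a replicate block (adjusted p = 0.0329). All these calls use the preset correlation. With an estimated correlation and all 6 arrays each of the 5 lists had an adjusted p of 0.975, and none of the 34 lists passed. With so few arrays that form has few degrees of freedom, so these failures alone say little against the lists. The estimated correlations were 0.475 for acute phase, 0.427 for immediate early, 0.372 for hepatocyte identity, 0.265 for cholesterol synthesis and 0.048 for pericentral genes, against the preset 0.01. How much of each loss came from correlation and how much from degrees of freedom was not tested. The mixed form of fry passed for glucose metabolism, the urea cycle and amino acid list, female-predominant genes, heme, pericentral, hepatocyte identity and endothelial markers. For targets of other xenobiotic sensors, 16 NRF2 targets had a median log2 difference of 0.10, with Txn1 at 0.30 ± 0.08 and Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, at 0.39 ± 0.11 (SE, adjusted p = 0.224 and 0.243 in limma). Adjusted over the list alone, 3 rose. The median was -0.21 over 3 AHR targets, with Cyp1a2 at -0.21 ± 0.19 and Tiparp at -0.23 ± 0.14, and -0.04 over 26 PPAR-alpha targets, with the fatty acid transporter Cd36 at 1.01 ± 0.21 (adjusted p = 0.141 in limma) and Pdk4 at -0.42 ± 0.16. A probe set annotated to both Cd36 and Cd36l1, which represents neither gene here, passed the threshold at 0.84 ± 0.12 (adjusted p = 0.0454 in limma), and is given after its value was seen. In the PPAR-alpha list, 1 gene rose when adjusted over the list alone. Heme synthesis and degradation had a median of 0.16 over 11 genes, with Blvra at 0.52 ± 0.13 and Cpox at -0.21 ± 0.09, and 1 rose over the list alone.

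Proliferation genes gave no call. Of 36 cell cycle genes, 34 had a probe set on the array and 9 were bright enough to be tested (median -0.18), with Pcna at 0.27 ± 0.12 and Mcm5, near the array median, at -0.47 ± 0.33, and 14 p53 and growth arrest genes had a median of -0.05, with Sesn1 at 0.32 ± 0.14 and Phlda3 at -0.68 ± 0.30. At an unadjusted p under 0.05 in limma neither list had a member.

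The lists of cholesterol, fatty acid, glucose and amino acid metabolism held no called gene. The median was 0.09 over 19 genes of cholesterol synthesis (Tm7sf2 0.49 ± 0.15, Nsdhl -0.30 ± 0.09) and -0.14 over 19 genes of fatty acid synthesis (Srebf1, its sterol-responsive transcription factor, -0.48 ± 0.13; Lpin1 0.74 ± 0.25). For 17 glucose genes it was -0.07, with Igfbp1, an insulin-repressed binding protein, at 1.25 ± 0.28 (adjusted p = 0.161 in limma) and Gpi at 0.32 ± 0.10; 1 rose over the list alone. For 26 genes of the urea cycle and amino acid breakdown it was -0.08, with Oat at -0.56 ± 0.11 (adjusted p = 0.136 in limma) and Hgd at -0.36 ± 0.10; 1 fell over the list alone.

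Hormone-dependent genes were mixed. Thyroid hormone response genes had a median of 0.00 over 10 genes (Me1 0.77 ± 0.26, Gpd2 -0.62 ± 0.26). Among 13 male-predominant liver genes the median was -0.09, with Obp3, a urinary protein of the male liver, at 5666 ± 1940 in control and 2426 ± 962 in treated livers (log2 -1.23 ± 0.32, adjusted p = 0.218 in limma) and Cyp2c13 at -0.17 ± 0.06. Among 8 female-predominant genes it was -0.15, with the prolactin receptor Prlr at 1.07 ± 0.22 (adjusted p = 0.136 in limma) and Sult1e1 at -0.30 ± 0.10. In the growth hormone axis it was -0.07 over 13 genes, with the repressor Bcl6 at 1.35 ± 0.28 (adjusted p = 0.144 in limma) and Cish at -1.01 ± 0.46. Over the list alone, 1 male-predominant gene fell, and 1 female-predominant and 1 growth hormone gene rose.

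Stress and inflammation lists had medians of -0.12 for 20 acute phase genes (Hpx -0.28 ± 0.07, A2m -0.71 ± 0.26), 0.03 for 20 genes of endoplasmic reticulum stress (Atf5 -0.99 ± 0.19, Herpud1 0.51 ± 0.18) and -0.10 for 9 heat shock genes (Hspd1 -0.20 ± 0.07, Dnaja1 -0.19 ± 0.09). They were -0.07 for 20 interferon response genes (Stat2 0.25 ± 0.10, Isg15 -0.47 ± 0.29), -0.09 for 12 clock genes (Nfil3 -0.23 ± 0.10, Cry1 -0.27 ± 0.12) and 0.31 for 10 immediate early genes (Klf6 0.64 ± 0.19, Jun 0.70 ± 0.26). In the list of endoplasmic reticulum stress, 1 gene fell over the list alone.

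Zonation and cell type markers were measured as a check on the makeup of the samples. Pericentral genes had a median of -0.16 over 12 genes, with Oat as above and Gulo at -0.44 ± 0.09, and 3 fell over the list alone. Periportal genes had -0.08 over 14 (Sds -0.77 ± 0.26, Cps1 -0.20 ± 0.07). Hepatocyte identity genes had -0.15 over 21 (Foxa3 -0.41 ± 0.13, Serpina1 -0.22 ± 0.07). Kupffer cell markers had -0.02 over 12 (Clec4f -0.33 ± 0.13, Csf1r -0.22 ± 0.12), stellate cell and matrix markers -0.11 over 14 (Col1a1 -0.27 ± 0.17, Dcn 0.27 ± 0.23) and endothelial markers 0.01 over 12 (Eng -0.45 ± 0.12, Lyve1 0.32 ± 0.14). Fewer markers were bright enough for cholangiocytes (0.63 over 3 genes, Epcam 0.63 ± 0.17, Onecut1 -0.85 ± 0.38, 1 higher over the list alone), lymphocytes and neutrophils (0.29 over 3, with Prf1 at 0.33 ± 0.30 and Cd4 at -0.30 ± 0.33, both near the array median), blood (-0.01 over 3, Slc4a1 -0.29 ± 0.25, Alas2 0.16 ± 0.21) and pancreas and fat (Cfd alone, -0.36 ± 0.20). In 8 of the 34 lists, among them bile acid synthesis, PPAR-alpha targets and Kupffer cell markers, the median, the mean and the direction of the camera test did not share a sign.

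Brightness moved with the groups. The 147 genes with a mean signal over 4000, to which many acute phase, hepatocyte identity and urea cycle genes belong, had a median log2 difference of -0.09, and 78.2% of them were lower in treated livers. Genes with a mean signal of 200 to 1000 had a median of 0.03. The 4 probe sets of the bacteriophage Cre transcript, a spiked-in hybridisation control, had log2 differences of -0.07 to -0.15, and the groups overlapped in 1 of them. None passed the threshold in a separate limma fit of the 57 control probe sets without an intensity trend (adjusted p of at least 0.751). Many of those 57 had signals near 0, so that fit says little about differences this small. The 14 probe sets of the bacterial hybridisation controls went both ways, from -0.08 to 0.07, with 5 higher and 9 lower.

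**Figure D3:**
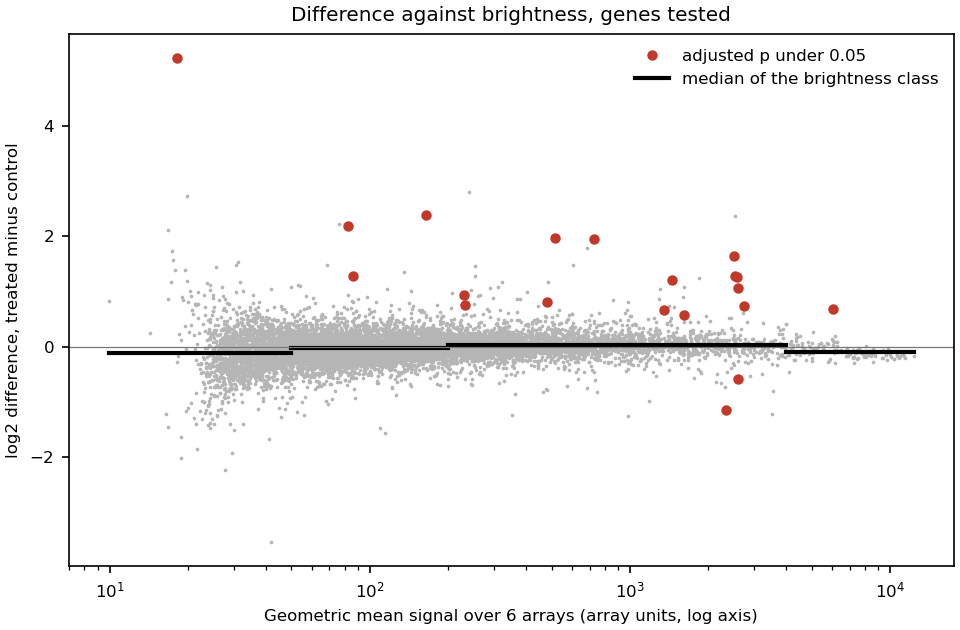
Log2 difference (treated minus control, vertical axis) against geometric mean signal over the 6 arrays (horizontal log axis, array units) for the 9200 genes tested; red points have a limma adjusted p under 0.05 and black bars are medians of brightness classes divided at 50, 200, 1000 and 4000. The medians are -0.12 in the dimmest class and -0.09 in the brightest, and lie at 0.03 in the classes from 200 to 4000.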

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

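The tests on the share of hepatocyte RNA, on the scaling, on brightness-matched lists, and on gene counts and the phase II list over other splits were chosen after the results they bear on had been seen.

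Signal past the threshold also appeared in 3 probe sets that the gene comparison does not use, because the annotation gives them no gene or several. Both probe sets with no gene symbol were higher in treated livers, by 1.22 and 0.62 on the log2 scale (adjusted p = 0.0451 and 0.0391 in limma), and a probe set annotated to Cd36 and Cd36l1 was higher by 0.84 (adjusted p = 0.0454 in limma); all 3 treated arrays were above all 3 control arrays in each.

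The 18 genes that rose, among them enzymes of drug metabolism, form the first pattern weighed. A larger share of hepatocyte RNA in the treated samples, as the whole cause, would raise hepatocyte genes together by about as much as these genes. The hepatocyte identity list did not rise with them: its median log2 difference was -0.15 with an SD of 0.21 over its 21 members. That cannot decide on the makeup of the samples, since hepatocytes are the main cells of liver and their share has little room to rise. The list is also bright (median signal 6460), and most genes that bright were lower in treated livers. The scaling of the arrays is argued against as the whole cause, since all 18 genes still passed after quantile normalization of the 6 arrays. Over the 10 splits of the arrays into 3 and 3, the real split gave 27 probe sets and 20 genes past the threshold. The highest other split gave 3 and 3, so that 1 split gave as many, and 10 splits are too few for a share under 0.05. Every other split holds arrays of both groups on each side, so a difference between the groups would itself lower its counts. The diet, which the design gives as the difference between the groups, stays among the open explanations.

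The call of the phase II list stands differently. Of the 10 splits, the real one included, 9 put at least as many lists past the preset camera threshold as the real one, which gave 1, and the highest other split gave 6. The cause of those larger counts was not tested. Every other split mixes the groups 2 to 1. No list passed in the real split with an estimated correlation, a form that few lists could pass with 6 arrays. The phase II list itself passed only in the real split, with an adjusted p of 0.000644 against 0.104 as the smallest in the others, so that 1 of 10 splits gave as small a value, and 10 splits are too few for a share under 0.05.

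The small falls of bright liver genes form another pattern, which a brightness-dependent difference between the arrays could produce. For acute phase genes the median of -0.12 lay at percentile 19.8 of 10000 random lists drawn from the 30 genes nearest in brightness. They thus fell about as far as other genes of that brightness, which the explanation predicts. After quantile normalization, which makes the bright ends of the arrays equal whatever the cause, the median was -0.01. Neither value can separate an array difference from a real fall of abundant liver transcripts. Only 147 genes had a mean signal over 4000, and many of them are such transcripts. The spiked-in Cre transcript is no liver transcript, and its group mean signals were 6194 to 11120. All 4 of its probe sets were lower in treated arrays (mean log2 difference -0.113), as an array difference predicts. The dimmer bacterial controls averaged -0.019. Cre is 1 transcript and does not exclude a real fall beside an array difference. For hepatocyte identity genes the median of -0.15 lay at percentile 2.45, too close to the bound of 2.5 to decide, and it was -0.04 after quantile normalization. With 200 neighbours, tried first, the percentiles were 2.4 and 0.11, but those neighbours had a median signal of 3720 and 3410 against 6270 and 6460 for the lists and so were not matched at the bright end. An effect of the diet on secreted liver proteins stays open and untested.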

How the results depend on the processing

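Quantile normalization within kept probe sets and camera with an intensity trend were chosen after seeing the data. No called gene changed sign in any alternative. With 18 genes higher, 2 lower, 27 probe sets and 12 genes changed at least 2-fold as reported, eBayes without the trend gave 2, 0, 3 and 2. Robust eBayes gave 8 genes lower and 44 probe sets. Genes lower numbered 1 without a filter or with median centring, and 4 with either quantile normalization or the mean of a gene's probe sets. Leaving out 1 array gave 3 to 19 genes higher, 1 to 2 lower, 5 to 28 probe sets and 4 to 16 genes of at least 2-fold. The lowest came without treated replicate 2, followed by treated replicate 3 (5, 2, 8 and 6) and treated replicate 1 (13, 1, 16 and 10). Without control replicate 1, 2 or 3, 19, 19 and 17 genes were higher, of which 15, 12 and 13 were among the 18. Only 1 of the 2 lower genes was called each time. The CAR and PXR list, at an adjusted p of 0.071, passed without a filter (0.00969), with a filter at the 30th percentile (0.0176), quantile normalization (0.0112, or 0.0104 within kept probe sets), a pseudocount of 16 (0.0418), the mean of probe sets (0.0458) and camera with an intensity trend (0.0234), did not pass with the others (up to 0.975 with an estimated correlation), and ranged from 0.0168 to 0.25 with 1 array left out. Phase II conjugation passed in each alternative run except the estimated correlation (0.302), at 0.00026 to 0.00426 with 1 array left out. Lists past the test numbered 1 to 5 with 1 array left out, 3 with the filter at the 70th percentile, 5 with the camera trend (acute phase 0.0128, pericentral 0.0378 and hepatocyte identity 0.0234 beside both lists above) and 2 with the replicate block (immediate early genes 0.0329). With all arrays kept, called genes passed in 6 (Reep6) to 12 of 12 alternatives. Of the 20 called genes, 4 passed whichever array was left out and 3 (Acsm2, Cyp8b1 and Macrod1) in no such fit. Among 65 named genes not called, 5 passed in some alternative, and 4 values of 1162 turned sign (Alas2 and Cyp3a9). The test direction of 16 lists turned in some alternative, in 57 of 644 values, none with a call. With the filter at the 70th percentile 8 named genes and 2 lists had no value, since no probe set was left. Apart from the stated cases the cause was not tested. With a replicate block, 10 genes were higher, 3 lower and 15 probe sets passed; same-numbered animals did not deviate together (r = -0.1, 0.105 and -0.065), and not every array correlated best with its own number. Without detection calls, signals near the array median of 23.1 to 29.4 are the least certain.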

Other observations

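The test of the translocation and glycosylation list and the scan of gene families were chosen after the gene results had been seen, as were the genes named here.

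Of the 18 genes that rose, 5 belong to no list and were outside the fixed naming rule. Aox1, a molybdenum enzyme that oxidises aldehydes and drugs, rose 1.66-fold, from 2137 ± 59.7 to 3557 ± 307 (SD, n = 3, adjusted p = 0.0142 in limma). Slc39a4, a zinc importer, rose 1.92-fold, from 168 ± 19.2 to 320 ± 13.3, and Apeh, a peptidase that removes acylated amino acids from peptides, rose 1.75-fold, from 364 ± 35.8 to 635 ± 14.3 (adjusted p = 0.0186 for both in limma). Macrod1, an ADP-ribose hydrolase, and Dap rose 1.69-fold and 1.59-fold (adjusted p = 0.0451 for both in limma). Macrod1 was lost whichever array was left out, and none of the 5 passed without treated replicate 2 or without treated replicate 3. Slc39a4 was also lost without treated replicate 1, Apeh passed only without control replicate 1 and Dap only without treated replicate 1.

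Gsta3, a glutathione transferase, had the largest log2 difference of the phase II list without passing the threshold, 2.81 ± 0.45, from 106 ± 58.5 to 650 ± 156 (SE and SD, n = 3, adjusted p = 0.0636 in limma); it passed without control replicate 3 (adjusted p = 0.0177) and with a pseudocount of 16 (0.0386). None of the other Cyp3a genes measured passed, with Cyp3a2 at -0.16 ± 0.07, Cyp3a18 at -0.23 ± 0.14 and Cyp3a9 at 0.03 ± 0.36 (adjusted p = 0.425, 0.578 and 0.982 in limma); the value of Cyp3a9 was 0.00 after quantile normalization and turned negative without control replicate 2 (-0.41), treated replicate 1 (-0.07) or treated replicate 3 (-0.01).

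For 4 genes a probe set other than the brightest passed the threshold, and all 4 fell there. In Kmt2d that probe set fell from 87.9 ± 22 to a dim signal in treated livers, at least 3.43-fold, while the brightest had a difference of -0.24 ± 0.10. In Rundc3a it fell from 94.6 ± 8.8 to a signal at or below the array median on 2 of the 3 treated arrays, at least 3.71-fold with low signals raised to the array median, and the brightest had -0.68 ± 0.15. Mup5, a major urinary protein, had values of -1.61 ± 0.23 for the probe set past the threshold and -0.63 ± 0.30 for the brightest; another, dim in treated livers, was at least 2.36-fold lower without passing (adjusted p = 0.111 in limma). The probe sets of Trim2 had -0.70 ± 0.10, -0.72 ± 0.12 and -0.39 ± 0.26, with the first past the threshold.

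Sec61b, part of the protein translocation channel, and Dad1, part of the oligosaccharyltransferase, stood at 0.52 ± 0.08 and 0.44 ± 0.08 without passing (adjusted p = 0.0636 and 0.113 in limma), next to Reep6, which rose. The hypothesis that genes of translocation and N-glycosylation at the endoplasmic reticulum may rise together was tested on 33 measured genes without these 3. Of the 33, 28 were higher, with a median log2 difference of 0.15 and an SD of 0.16, and camera with an estimated correlation gave p = 0.129. The preset correlation gave p = 2.23e-06, but other splits among the 10 gave a p as small as 1.93e-06 and a median as far from 0 as 0.15, so splits that mix the groups moved these genes about as far and the hypothesis stays open.

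Gene families defined by the letters that open their symbols, with at least 8 tested members, gave no call in 137 camera tests at the preset correlation or with an estimated one, while 19 had an unadjusted p under 0.05 at the preset correlation. The smallest adjusted p was 0.0923, shared by the Adam, Akr, Sec and Mrps families; 10 of 13 aldo-keto reductase genes were higher, with a median log2 difference of 0.14.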
